A study of Levilactobacillus brevis with 12 samples.

How the data were processed

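RNA from Lactobacillus brevis UCCLBBS124 and UCCLBBS449 was compared on 12 2-colour Agilent arrays. Cultures were grown at 30 degrees in MRS broth or in MRS broth with 5% ethanol, at pH4 or with 30 ppm iso-α-acids, per the labels. Each array held a control and a stress sample of one strain, labelled with Cy3 and Cy5, and each of the 6 comparisons had 2 arrays with the dyes exchanged. The 12 arrays came from 3 slides of 4, per the file headers. One slide held UCCLBBS124 ethanol and pH4, the next both iso-alpha-acid comparisons, and the last UCCLBBS449 ethanol and pH4. Groups, the channel that held the stress sample and its dye were taken from the labels, and the arrays of a group were numbered in deposition order.

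The authors deposited 1 scanner file per array and a table of values for the whole series. Per the file headers the scanner files came from Agilent Feature Extraction 9.1.1.1, while the submitters' processing notes give version 9.5. The mean signal and the local background of each spot are in intensity units per the file headers. The deposited log ratio is the log10 of the red over the green signal after the background subtraction and dye normalisation of Feature Extraction. The other columns used, per the file headers, are yes or no flags for a spot well above background, saturated or an outlier. The deposited series table was tested against the log ratio column and was identical to it (largest difference 0, column medians 0). It is not turned for the exchanged dyes, and it was turned here. Every array had 45220 spots, of which 43803 were gene spots. The gene spots belonged to 19999 probes of 60 bases, each spotted 2 to 3 times, and to 3017 locus tags with 1 to 8 probes (median 8). There were 300 probe sequences assigned to more than 1 locus tag, which touched 185 genes. At most 9 gene spots per array were marked as outliers and left out, and at most 22 were saturated in the red channel and kept.

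Mean signals were corrected with the normexp method (offset 50) and normalised within each array by loess (span 0.3, 4 iterations) in limma 3.58.1 under R 4.3.3 with version 1.17.8 of data.table. Spots of one probe were averaged, and the value of a gene was the median over its distinct probes. A gene entered a strain's fit when, under at least 1 stress, a share of at least 0.5 of its probes lay well above background in one channel on both arrays. The log2 ratios of the 6 arrays of a labelled strain were fitted with 1 coefficient per stress and 1 gene-specific dye term, followed by eBayes. The median residual SD after eBayes was 0.0761 for UCCLBBS124 and 0.0427 for UCCLBBS449. It combined 2 residual with 4.82 and 4.31 prior degrees of freedom, in that order. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. The same counts came from averaging the 2 arrays without a test, so the fold threshold and not the test set them. Strain differences were contrasts in a fit of all 12 arrays, with the same thresholds, over genes that entered both fits. Channel levels for the comparison of channels were the within-array normalised intensities, with the mean signal of both channels quantile-normalised between arrays.

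The number of arrays limits the precision, and dim genes are limited by signal over background. Between 2419 and 2713 of the 3017 genes lay above background on the arrays of a comparison. Dixon's rule and other splits of the samples do not apply to groups of 2 arrays. The procedure was tested on simulated data with the real layout: over 6 comparisons, 100% of genes given a change of 1.5 or 2.5 on the log2 scale were called in the right direction, as were 0% of genes given 0.5 and 0% of unchanged genes. The simulated noise was the fitted residual spread, far smaller than the distance of these sizes from the fold threshold. The outcome was therefore fixed by the sizes chosen, and it checks the calculation only.

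The comparisons, tests, thresholds, alternatives and the rule for named genes were set before the data were examined. The rule names, per comparison, called genes that moved the same way on both arrays, by the size of the change and with a gene name or product. Because the files and the reference gave no names for these locus tags, its fallback applied, at most 2 tags that were higher and 2 that were lower. The 21 gene lists fixed with it were not run, since none of the locus tags could be joined to a name. Of 2471 genes in the reference table, 0 carried one of these tags. Tests of tag groups (camera with a preset correlation of 0.01 and with an estimated one, and fry) and of runs of neighbouring tags (10000 permutations of the calls within a tag group) were added later. The alternatives tried were the Feature Extraction log ratio, the series table, median centring, loess on probes above background, no background subtraction, offset 16, no filter, the mean over probes, no dye term, a dye term per slide, 1 fit of all arrays, a fold of at least 3, adjusted p alone, both arrays averaged, and leaving out each array. Further alternatives added after the data were seen left out the 4 arrays whose strain tags went against the label, probes shared between genes, genes below background on a comparison's own arrays, or the arrays of other slides.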

Results

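Transcript levels of the Lactobacillus brevis (now Levilactobacillus brevis) strains UCCLBBS124 and UCCLBBS449 were measured in plain MRS broth and in MRS broth under 3 stresses. The stresses were 5% ethanol, pH4 and 30 ppm iso-α-acids, the bitter acids of hops. Each of the 6 comparisons of a stress with the control consisted of 2 arrays that carried the same pair of conditions with the dyes exchanged, which gave 12 arrays. One array design held 43803 gene spots for 19999 probes of 3017 locus tags from both genomes. The median spot signal was 299 to 888 intensity units in the channels labelled stress and 109 to 793 in the channels labelled control. The number of arrays limits the precision. The labels do not say whether the 2 arrays of a comparison came from separate cultures. The p-values measure only the spread between arrays that is left after the dye term, which may be technical. That term takes up any difference between an array and its dye swap that the 3 comparisons of a label have in common. An SE can thus be far below the spread of the 2 arrays. On the arrays labelled UCCLBBS124 iso-alpha-acids, UCCLBBS449_0139 had log2 ratios of -2.60 and -3.98 with an SE of 0.170. None of the locus tags was found in the reference gene table of 2471 genes (0 matches), and genes are therefore given by locus tag, without names or positions.

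Hybridisation did not follow the strain labels on 4 of the 12 arrays. Probes for UCCLBBS449 tags with the letters pF to pI (169 probes found in no other gene) lay well above background for 99.4% ± 1.19 (SD over 4 channels, 2 arrays) on the arrays labelled UCCLBBS124 ethanol. This share was 99.4% and 100% on the arrays labelled UCCLBBS449 ethanol and UCCLBBS449 pH4. It was 28.7% and 10.4% on the arrays labelled UCCLBBS124 pH4 and UCCLBBS124 iso-alpha-acids, and 10.4% ± 1.71 on the arrays labelled UCCLBBS449 iso-alpha-acids. Probes for plain-number UCCLBBS124 tags (1660 probes) gave the complementary picture, with 87.8%, 77.5% and 79.2% above background on the arrays labelled UCCLBBS124 pH4, UCCLBBS124 iso-alpha-acids and UCCLBBS449 iso-alpha-acids. The share was 26.4%, 36.7% and 39.2% on the arrays labelled UCCLBBS124 ethanol, UCCLBBS449 ethanol and UCCLBBS449 pH4. The 2 arrays labelled UCCLBBS124 ethanol differed, with 40.5% and 12.3%. Against the 95th percentile of negative control spots, the 3 shares were 44.9%, 59.7% and 62.5%, and the 3 higher ones 93.9%, 90.1% and 91.1%. The arrays labelled UCCLBBS124 ethanol thus carried UCCLBBS449 sequence, and those labelled UCCLBBS449 iso-alpha-acids carried UCCLBBS124 sequence. Groups are named here by their labels throughout, and which stress those 2 comparisons held was not determined. The control treatment label of the UCCLBBS449 arrays also names UCCLBBS124. The plan for this check named strain-unique probes without giving letters, and pF to pI were picked from the UCCLBBS449 letters. Of the letters left out, 57 of 71 pA, 20 of 31 pC and 16 of 21 pD genes were above background on the arrays labelled UCCLBBS124 pH4. The choice of letters thus bears on how far the pF to pI shares separate the arrays.

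**Figure D1:**
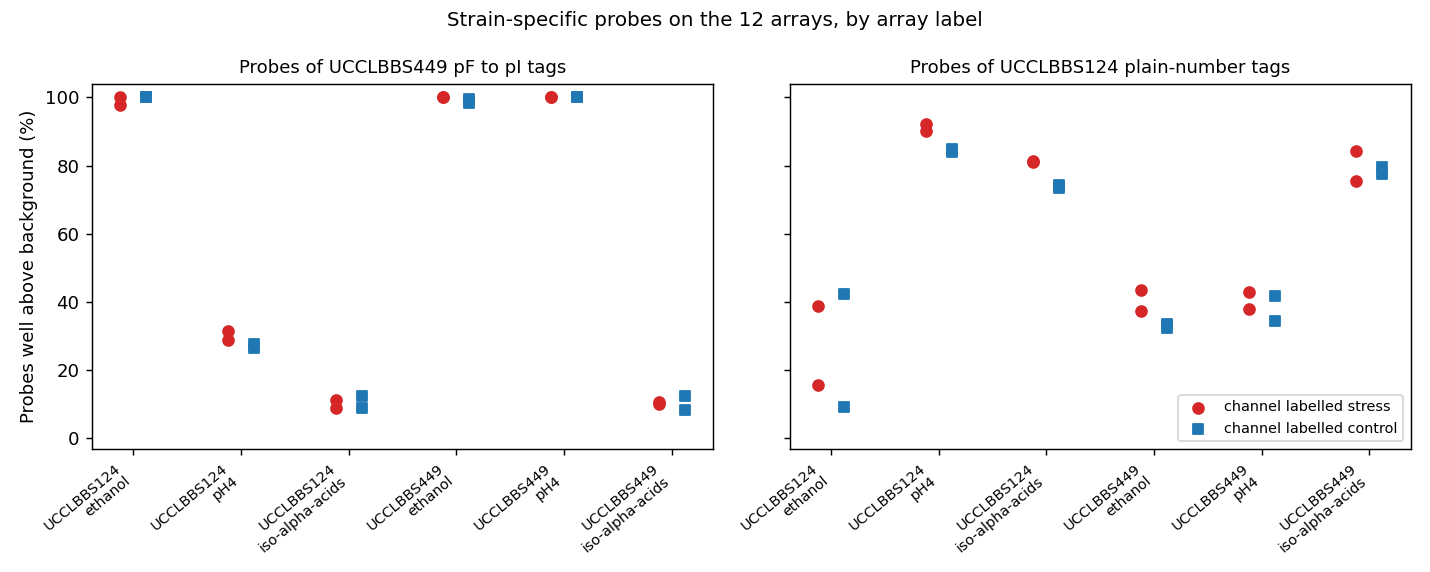
Percentage of strain-specific probes well above background (y axis) on the arrays of each label (x axis), with 1 point per array and channel, for 169 probes of UCCLBBS449 pF to pI tags and 1660 probes of plain-number UCCLBBS124 tags. The arrays labelled UCCLBBS124 ethanol lie with the other UCCLBBS449 arrays (mean 99.4% in the left panel), and those labelled UCCLBBS449 iso-alpha-acids lie with the UCCLBBS124 arrays (mean 79.2% in the right panel).

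The channels labelled stress were nearly alike under different stresses, while the channels labelled control differed. Between the arrays labelled UCCLBBS124 pH4 and UCCLBBS124 iso-alpha-acids, 0 of 2453 genes differed by at least 2-fold in the stress-labelled channel and 167 did in the control-labelled channel. The SD of the log2 difference was 0.150 and 0.617, and the correlation across genes was 0.995 and 0.918, in that order. Between the arrays labelled UCCLBBS449 ethanol and UCCLBBS449 pH4 the counts were 0 and 63 of 2644 genes, and the SDs were 0.0932 and 0.400. These correlations are across genes, which are not independent replicates. All directions below are therefore written as higher or lower in the channel labelled stress. If the labels of the 2 channels were exchanged, every direction would turn while sizes and counts would stand.

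**Figure D2:**
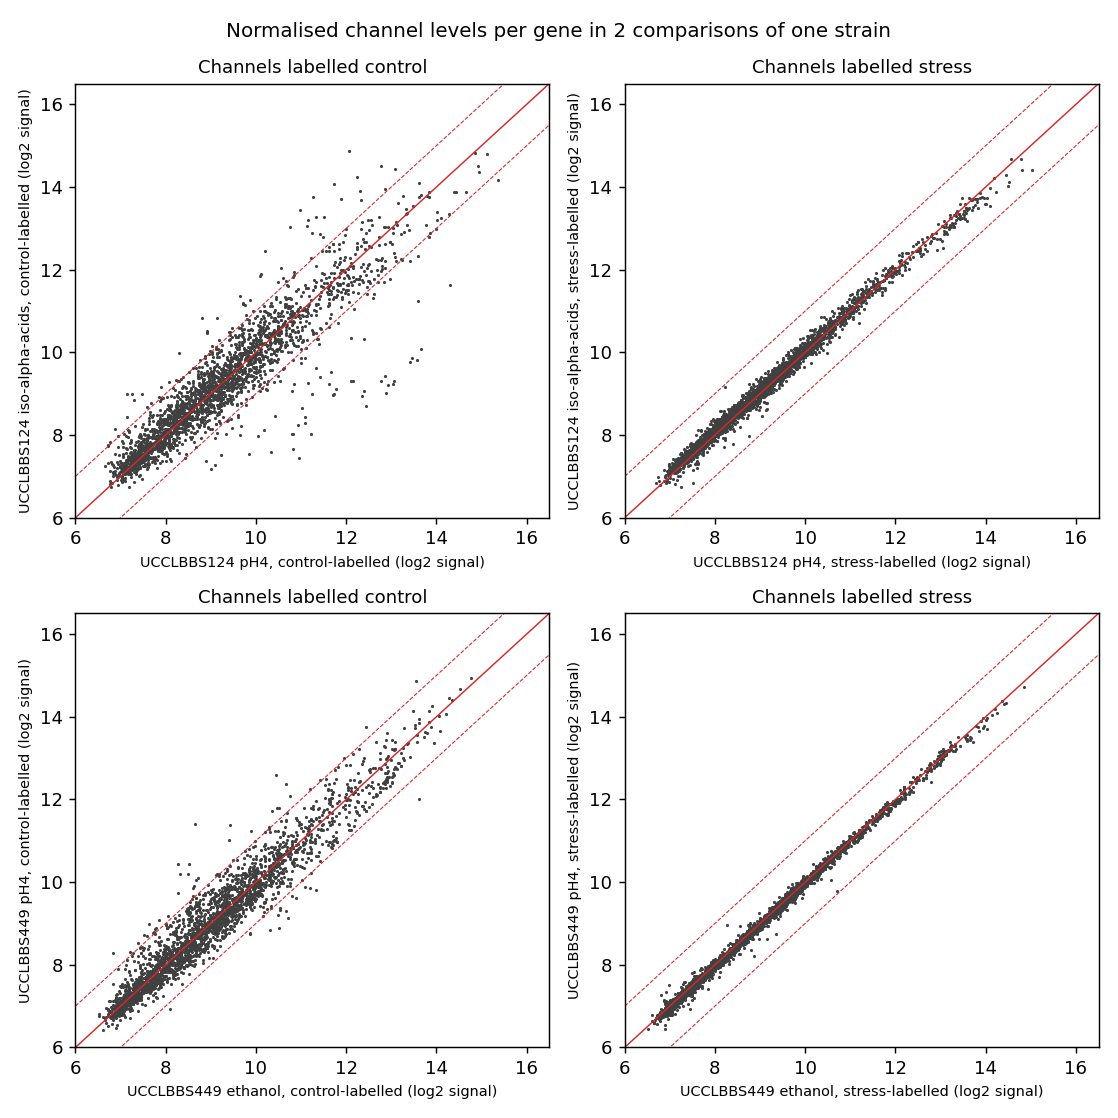
Normalised level of each gene above background (log2 signal, mean of the 2 arrays) in the control-labelled channel (left) and the stress-labelled channel (right) of 2 comparisons of one strain, with UCCLBBS124 pH4 against iso-alpha-acids on top and UCCLBBS449 ethanol against pH4 at the bottom. The solid line marks equal levels and the dashed lines a 2-fold difference, which 167 and 63 genes passed in the control-labelled channels and 0 in the stress-labelled channels.

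Ethanol addresses how cells meet the alcohol of beer. On the arrays labelled UCCLBBS124 ethanol, 69 genes were higher and 99 were lower in the channel labelled stress, or 161 and 200 with the Feature Extraction log ratio. UCCLBBS449_0177 (log2 2.59 ± 0.0518 SE, n = 2 arrays, limma adjusted p = 1.09e-06) and UCCLBBS449_0654 (2.35 ± 0.0495, adjusted p = 1.09e-06) were highest. UCCLBBS449_2369 (-2.60 ± 0.0686, adjusted p = 2.02e-06) and UCCLBBS449_2144 (-2.45 ± 0.0633, adjusted p = 2.02e-06) were lowest. One of the probes of UCCLBBS449_0177 is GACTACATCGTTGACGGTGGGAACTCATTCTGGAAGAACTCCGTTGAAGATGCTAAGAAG. Neighbouring tags moved together, among them 13 lower genes from UCCLBBS449_1633 to UCCLBBS449_1645 (median -1.25), 10 lower genes from UCCLBBS449_1614 to UCCLBBS449_1623 (median -1.41) and 5 higher genes from UCCLBBS449_1715 to UCCLBBS449_1719 (median 1.64). These runs, like every run of tags named below, were chosen after their values were seen. Of the 168 called genes of 2886 tested, all 168 moved the same way on both arrays, and the correlation across genes between the 2 arrays was 0.849. The direction of this comparison depended on the normalisation: with median centring in place of loess, 187 genes were higher and 27 were lower. These are the arrays that carried UCCLBBS449 sequence.

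Acid, labelled pH4, gave 225 called genes under the label UCCLBBS124 and 14 under the label UCCLBBS449. The counts were 331 and 32 with the Feature Extraction log ratio, and 1751 and 1621 with the limma adjusted p alone. On the arrays labelled UCCLBBS124 pH4, 74 genes were higher and 151 were lower in the channel labelled stress, or 146 and 185 with the Feature Extraction log ratio. UCCLBBS449_0146 (3.07 ± 0.133 SE, n = 2 arrays, limma adjusted p = 3.11e-06) and UCCLBBS449_2308 (2.93 ± 0.0627, adjusted p = 1.28e-07) were highest. The adjacent tags UCCLBBS449_2143 (-3.70 ± 0.0694, adjusted p = 1.02e-07) and UCCLBBS449_2142 (-3.67 ± 0.0754, adjusted p = 1.15e-07) were lowest, 13.0 and 12.7 times below the channel labelled control. A probe of UCCLBBS449_2143 is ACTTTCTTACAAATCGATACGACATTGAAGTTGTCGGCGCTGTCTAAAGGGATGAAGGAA. The clearest runs were 4 lower genes from UCCLBBS449_2141 to UCCLBBS449_2144 (median -3.64), 5 lower genes from UCCLBBS449_0205 to UCCLBBS449_0209 (median -2.88) and 4 higher genes from UCCLBBS449_2306 to UCCLBBS449_2309 (median 2.83). Longer runs were 18 lower genes from UCCLBBS124_1394 to UCCLBBS124_1411 (median -1.31) and 11 lower genes from UCCLBBS449_1407 to UCCLBBS449_1417 (median -1.57). There were also 8 higher genes from UCCLBBS124_0459 to UCCLBBS124_0466 (median 1.72) and 8 from UCCLBBS449_1822 to UCCLBBS449_1829 (median 1.09). The 225 called genes moved the same way on both arrays, with a correlation across genes of 0.968.

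Iso-α-acids are known to act on the bacterial cell membrane. On the arrays labelled UCCLBBS124 iso-alpha-acids, 52 genes were higher and 31 were lower in the channel labelled stress, or 95 and 56 with the Feature Extraction log ratio. UCCLBBS449_1416 (2.06 ± 0.0782 SE, n = 2 arrays, limma adjusted p = 5.63e-06) and UCCLBBS449_2172 (2.05 ± 0.109, adjusted p = 1.57e-05) were highest. UCCLBBS449_0139 (-3.29 ± 0.170, adjusted p = 1.39e-05) and UCCLBBS449_0685 (-2.27 ± 0.0831, adjusted p = 5.49e-06) were lowest. A probe of UCCLBBS449_1416 is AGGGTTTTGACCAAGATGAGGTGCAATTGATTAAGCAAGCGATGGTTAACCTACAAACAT. More of the higher genes lay in 2 stretches than elsewhere: 22 genes from UCCLBBS449_1808 to UCCLBBS449_1829 (median 1.63) and 15 genes from UCCLBBS449_1403 to UCCLBBS449_1417 (median 1.91). The first stretch also had a median of 0.96 on the arrays labelled UCCLBBS124 pH4, with 9 of its genes called. The second stretch had a median of -1.52 there, with 11 genes called lower. Its median log2 level was 11.17 and 11.09 in the stress-labelled channels of iso-alpha-acids and pH4, against 9.23 and 12.77 in the control-labelled channels. All 83 called genes moved the same way on both arrays, with a correlation across genes of 0.845.

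**Figure D3:**
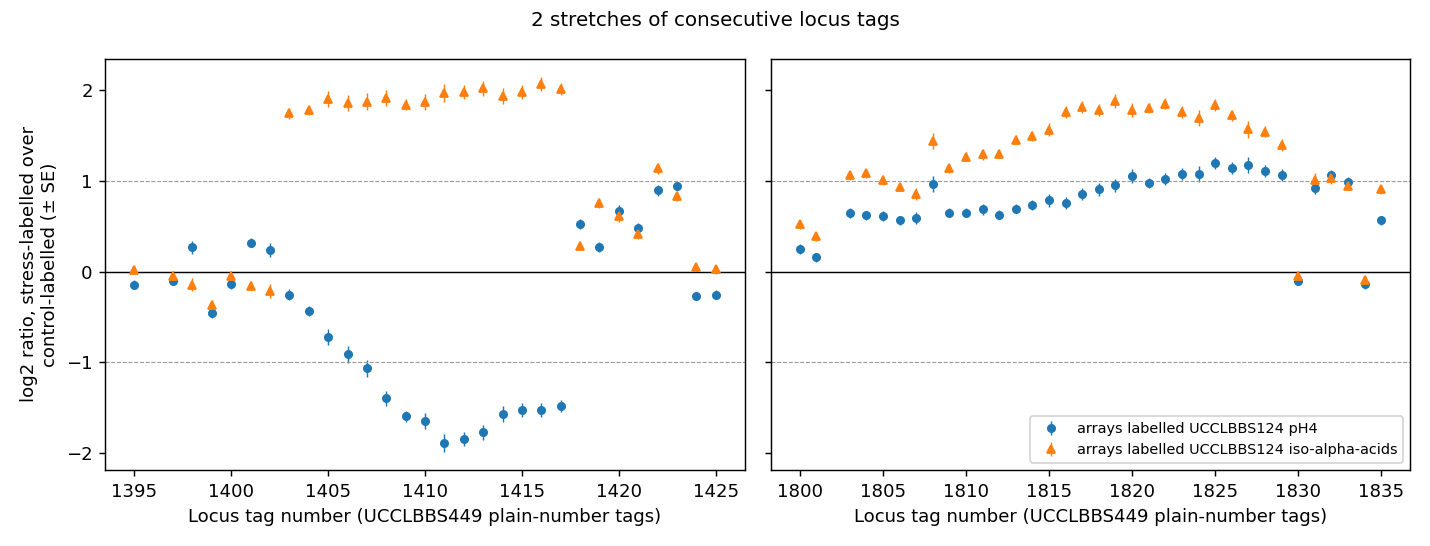
Fitted log2 ratio of the stress-labelled over the control-labelled channel (y axis, error bars SE, n = 2 arrays) along consecutive UCCLBBS449 plain-number tags (x axis), on the arrays labelled UCCLBBS124 pH4 and UCCLBBS124 iso-alpha-acids, with dashed lines at a 2-fold change. The 15 genes of the left stretch had a median of 1.91 under iso-alpha-acids and -1.52 at pH4, and the 22 genes of the right stretch had medians of 1.63 and 0.96.

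For the arrays labelled UCCLBBS449 ethanol, 28 genes were higher and 4 were lower in the channel labelled stress, or 90 and 9 with the Feature Extraction log ratio. UCCLBBS449_2334 (1.94 ± 0.0314 SE, n = 2 arrays, limma adjusted p = 7.59e-07) and UCCLBBS449_0730 (1.78 ± 0.0309, adjusted p = 7.59e-07) were highest. UCCLBBS449_pD0004 (-1.31 ± 0.0371, adjusted p = 3.30e-06) and MB124-5_0023 (-1.29 ± 0.0311, adjusted p = 2.25e-06) were lowest. MB124-5_0023 shared 7 of its 8 probes with UCCLBBS449_pD0003 (-1.26), so the 2 values are not independent. The remaining lower gene was UCCLBBS449_2036 (-1.20), and these last 2 genes were chosen after their values were seen. A probe of UCCLBBS449_2334 is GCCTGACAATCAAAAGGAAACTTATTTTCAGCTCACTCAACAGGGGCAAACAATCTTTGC. Of 2892 genes tested, 32 were called, all with the same direction on both arrays.

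The arrays labelled UCCLBBS449 pH4 had 1 gene higher and 13 lower in the channel labelled stress, or 4 and 28 with the Feature Extraction log ratio. The higher gene was UCCLBBS449_0147 (1.01 ± 0.0324 SE, n = 2 arrays, limma adjusted p = 7.15e-06), which lay just past the fold threshold and gave 0.95 without replicate 1 and 0.99 without background subtraction. UCCLBBS449_1898 (-1.82 ± 0.0275, adjusted p = 9.48e-07) and UCCLBBS449_0582 (-1.34 ± 0.0275, adjusted p = 3.26e-06) were lowest. A probe of UCCLBBS449_1898 is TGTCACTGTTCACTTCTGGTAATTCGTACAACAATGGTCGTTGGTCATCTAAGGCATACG. The 5 genes from UCCLBBS449_1895 to UCCLBBS449_1899 were all lower (median -1.29). The 14 called genes of 2892 moved the same way on both arrays.

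On the arrays labelled UCCLBBS449 iso-alpha-acids, 57 genes were higher and 15 were lower in the channel labelled stress, or 118 and 37 with the Feature Extraction log ratio. UCCLBBS449_2080 (2.43 ± 0.0309 SE, n = 2 arrays, limma adjusted p = 1.06e-07) and UCCLBBS449_2376 (2.38 ± 0.0361, adjusted p = 1.39e-07) were highest. UCCLBBS449_0358 (-3.14 ± 0.0268, adjusted p = 2.57e-08) and UCCLBBS449_2036 (-2.48 ± 0.0448, adjusted p = 2.23e-07) were lowest. A probe of UCCLBBS449_0358 is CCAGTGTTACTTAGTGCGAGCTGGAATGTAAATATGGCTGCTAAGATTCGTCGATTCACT. Adjacent higher genes were UCCLBBS449_0564 to UCCLBBS449_0566 (3 genes, median 1.87) and UCCLBBS449_0207 to UCCLBBS449_0210 (4 genes, median 1.46). All 72 called genes of 2892 moved the same way on both arrays. These are the arrays that carried UCCLBBS124 sequence.

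**Figure D4:**
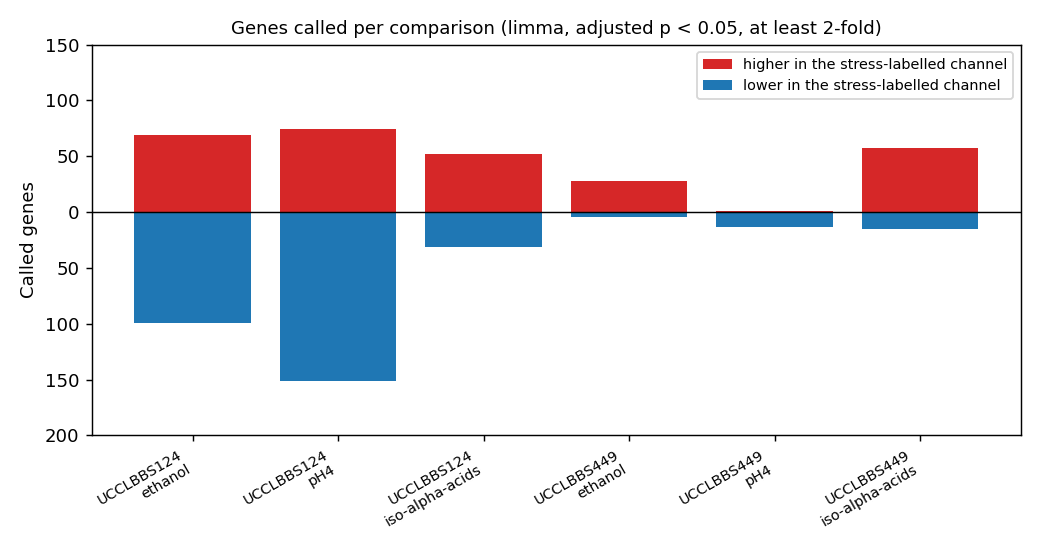
Number of genes called per comparison (y axis, limma adjusted p under 0.05 and at least 2-fold, 2 arrays per comparison), split into genes higher (above 0) and lower (below 0) in the channel labelled stress. Arrays labelled UCCLBBS124 pH4 gave 225 called genes and arrays labelled UCCLBBS449 pH4 gave 14.

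Called genes lay next to each other on the locus tag order more often than chance placement gave. On the arrays labelled UCCLBBS124 ethanol, pH4 and iso-alpha-acids, 53, 107 and 44 adjacent pairs of tags were called in one direction, where random placement within a tag group gave means of 6.63, 10.2 and 1.44. For UCCLBBS449 ethanol, pH4 and iso-alpha-acids, again by label, the pairs numbered 4, 5 and 16, against means of 0.554, 0.0657 and 1.24. The one-sided permutation p was 9e-04 for UCCLBBS449 ethanol and 1e-04 for the other 5 comparisons, which is the smallest that 10000 permutations can give. Genes with shared probes were counted as separate genes. At UCCLBBS124 pH4, the runs UCCLBBS124_1389 to UCCLBBS124_1392 and UCCLBBS124_1462 to UCCLBBS124_1465 held 13 shared probes each. Placement also ran over all genes of a label's fit. For UCCLBBS124 ethanol these were 2886 genes, of which 2419 were above background on its arrays, which lowers the chance mean. Runs of at least 3 tags held 48% of the called genes on the arrays labelled UCCLBBS124 pH4, 51.8% under iso-alpha-acids and 29.8% under ethanol. For UCCLBBS449 they held 0% under ethanol, 35.7% at pH4 and 9.72% under iso-alpha-acids.

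The response of both labelled strains to one stress was compared by the difference of the log2 ratios, UCCLBBS449 minus UCCLBBS124, over 2848 genes. At pH4, where the arrays carried the genome of their label, 145 genes had a higher and 63 a lower ratio in UCCLBBS449, or 180 and 127 with the Feature Extraction log ratio. Some of these genes carried UCCLBBS124 tags mostly at background on the arrays labelled UCCLBBS449 pH4. They entered that label's fit through its iso-alpha-acid arrays, which carried UCCLBBS124 sequence. The 18 genes from UCCLBBS124_1394 to UCCLBBS124_1411 had medians of -1.31 in UCCLBBS124 and 0.02 in UCCLBBS449, where 5 were above background. Such differences set a ratio against background, and their number was not counted. UCCLBBS449_0258 differed by 3.72 ± 0.0743 (SE, n = 2 arrays per strain, limma adjusted p = 6.87e-09), from -3.55 in UCCLBBS124 to 0.18 in UCCLBBS449. UCCLBBS449_2143 differed by 3.65 ± 0.0826 (adjusted p = 1.18e-08), from -3.70 to -0.05. UCCLBBS449_0146 went from 3.07 to -1.14, a difference of -4.21 ± 0.182 (adjusted p = 3.50e-07), and UCCLBBS449_2308 from 2.93 to 0.01, a difference of -2.91 ± 0.0756 (adjusted p = 2.20e-08). The pH4 arrays of the 2 strains lay on different slides, so strain and slide cannot be told apart.

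For ethanol, 159 genes had a higher and 75 a lower ratio on the arrays labelled UCCLBBS449, with median centring 91 and 179, and with the Feature Extraction log ratio 335 and 229. UCCLBBS449_0138 (difference 3.47 ± 0.0742 SE, n = 2 arrays per strain, limma adjusted p = 4.05e-08) was lower in the channel labelled stress on one side (-2.17) and higher on the other (1.30). UCCLBBS449_2144 differed by 3.09, UCCLBBS449_0177 by -2.58 and UCCLBBS449_2104 by -2.18. For iso-alpha-acids, 152 genes had a higher and 95 a lower ratio, which median centring turned to 118 and 128 and the Feature Extraction log ratio to 246 and 182. UCCLBBS449_1693 went from -1.60 to 1.92 (difference 3.52 ± 0.0879 SE, n = 2 arrays per strain, limma adjusted p = 1.17e-07) and UCCLBBS449_2151 from -1.76 to 1.07. UCCLBBS449_0358 differed by -2.39 and UCCLBBS449_1411 by -2.06. All arrays of the ethanol difference carried UCCLBBS449 sequence and all of the iso-alpha-acid difference carried UCCLBBS124 sequence, so neither compares 2 genomes.

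Several genes were called in more than 1 comparison. Of 458 genes called at least once, 112 were called in at least 2 comparisons and 7 in 4. Ethanol and pH4 shared 36 genes in one direction on the arrays labelled UCCLBBS124, where independent lists would share 6.95, and pH4 and iso-alpha-acids shared 32 (2.96 if independent). A further 12 genes were lower at pH4 and higher under iso-alpha-acids, of which 11 were the run from UCCLBBS449_1407 to UCCLBBS449_1417. Under the label UCCLBBS449, ethanol and iso-alpha-acids shared 7 genes (0.573 if independent), and 9 of the 14 genes called at pH4 were called in the opposite direction under iso-alpha-acids. Between the labelled strains, pH4 shared 7 lower genes (0.689 if independent), among them UCCLBBS449_2368 (-2.78 and -1.25) and UCCLBBS449_2369 (-2.37 and -1.20). Iso-alpha-acids shared 7 genes (1.20 if independent), among them UCCLBBS449_0685 (-2.27 and -1.37). Ethanol shared 1 gene, UCCLBBS449_2382 (1.65 and 1.41), and had 3 in opposite directions, which were UCCLBBS449_0138, UCCLBBS449_pH0004 and UCCLBBS449_pH0005. UCCLBBS449_2368, UCCLBBS449_2382, UCCLBBS449_pH0004 and UCCLBBS449_pH0005 were chosen after their values were seen. In 20 simulations of unchanged genes, with part of the array variance shared between comparisons and the spread of the UCCLBBS124 arrays, a mean of 0 genes was called in common. As the simulated spread was far below the fold threshold, this 0 was fixed in advance and gives no baseline for the overlaps. The simulation covers noise between arrays only, and not a sample that differs and is shared by 2 comparisons. No p was computed for the excess over independent lists, and comparisons whose stress-labelled channels were alike are not independent of each other. By hybridisation, ethanol and pH4 under the label UCCLBBS124 carried different genomes. So did iso-alpha-acids and the other stresses under the label UCCLBBS449. Those overlaps therefore do not compare 2 stresses of 1 strain.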

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

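The counts and values of the strain differences came from tests planned in advance, while all tests that weigh an explanation here were chosen after the result was seen. The response of the labelled strains differed in 234 genes for ethanol, 208 for pH4 and 247 for iso-alpha-acids (limma, UCCLBBS449 minus UCCLBBS124). The pH4 count includes UCCLBBS124 tags that were mostly at background on the arrays labelled UCCLBBS449 pH4, which show no response to compare. The ethanol and iso-alpha-acid counts do not compare the strains, because both pairs of arrays carried sequence of the same genome. Between the ethanol pairs, 0 of 2411 genes differed by at least 2-fold in the stress-labelled channel and 264 in the control-labelled channel. Between the iso-alpha-acid pairs the counts were 0 and 246 of 2407 genes. At pH4 the log2 difference was 3.72 for UCCLBBS449_0258, 3.65 for UCCLBBS449_2143, -4.21 for UCCLBBS449_0146 and -2.91 for UCCLBBS449_2308. The check of strain labels, which is separate from the comparisons of stress with control, found signal for tags of the strain that a label does not name, although genes with such tags also entered the comparisons. In the pair labelled UCCLBBS124 ethanol, 99.4% of the UCCLBBS449 pF to pI probes were above background, and in the pair labelled UCCLBBS449 iso-alpha-acids 79.2% of the plain-number UCCLBBS124 probes were.

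The first pattern is that these 2 pairs of arrays hybridised as the other strain. Cross-hybridisation is argued against, because at most 31.4% of the pF to pI probes were above background in any channel of the other arrays labelled UCCLBBS124 (43.2% against the 95th percentile of negative controls). Mixed RNA of both strains is argued against for the pair labelled UCCLBBS449 iso-alpha-acids, because at most 12.4% of the pF to pI probes were above background there (29.6% against negative controls, below the 43.2% on arrays labelled UCCLBBS124 pH4). For the pair labelled UCCLBBS124 ethanol it stays open. At most 42.2% of the plain-number UCCLBBS124 probes were above background there, against at most 43.4% on the arrays labelled UCCLBBS449 ethanol and pH4. Against negative controls the values were 65.8% and 64.7%. An exchange of the 2 pairs of arrays, or of their labels, is a candidate explanation. At least 75.5% of the plain-number UCCLBBS124 probes were above background on the arrays labelled UCCLBBS449 iso-alpha-acids. On the arrays labelled UCCLBBS449 ethanol and pH4 at most 43.4% were. Those shares belong to the pattern itself, and separate errors in each pair would also give them. They therefore do not single out an exchange. Which stress these 2 pairs held was not determined and stays open, and no biological explanation was tested.

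The second pattern is that the stress-labelled channel was alike in all comparisons that hybridised as one genome. Over the 6 such pairs of comparisons, 0 genes differed by at least 2-fold between stress-labelled channels and 63 to 376 did between control-labelled channels. Normalisation that made one channel alike is argued against, because without loess and quantile steps the SD between stress-labelled channels was at most 0.289 of that between control-labelled channels. Exchanged channel labels are a candidate explanation, since the stress-labelled channels correlated across genes at 0.995 or more, which a shared control RNA in that channel would give. The control-labelled channels correlated at 0.869 to 0.968. For the stress-labelled channel of an array and its dye swap, the range was 0.989 to 0.998. That range is between single arrays and the other values between means of 2 arrays, so they are not like for like. The same profile under all 3 stresses beside control cultures that differed, by 63 genes or more, cannot be told apart from exchanged channel labels, because the files hold no other sample of either condition.

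The third pattern is that the direction of the calls on the arrays labelled UCCLBBS124 ethanol turned with the centring, from 69 higher and 99 lower genes to 187 and 27 with median centring. Loess and median centring differ only in that loess removes a dependence of the log ratio on signal level. Some such dependence was therefore bound to appear where the calls turned. The median-centred ratio correlated with the mean signal across genes on both arrays (Spearman 0.496 and 0.746). These values describe the dependence and are no separate support for it as the cause. No other pair passed 0.3 with one sign on both arrays: the values were 0.643 and 0.265 for UCCLBBS449 ethanol, and 0.626 and -0.107 for UCCLBBS449 pH4. A change in the cells that falls on strongly expressed genes would give the same trend and stays open, as untested.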

How the results depend on the processing

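The settings that leave out conflicting arrays, shared probes, genes below background on a comparison's own arrays or other slides were chosen after the data were seen, and the others were planned. A count was taken as kept when its total stayed within 1.5 times the main one, whatever its directions, and a share when it moved by at most 1 SD between channels. By this, 204 values were kept and 60 moved. Of the values of named genes, 499 stayed past their threshold and 6 fell short, all in the same direction, and 0 turned. Outside changes of threshold, an alternative kept at least 53.0% of the called genes of a comparison. With median centring, calls on the arrays labelled UCCLBBS124 ethanol turned from 69 higher and 99 lower to 187 and 27 (89 of the 168 calls kept), the ethanol difference from 159 and 75 to 91 and 179, and the iso-alpha-acid difference from 152 and 95 to 118 and 128. With the Feature Extraction ratio the pH4 split was 146 higher and 185 lower on the arrays labelled UCCLBBS124 and 180 and 127 in the strain difference, against 74 and 151, and 145 and 63. Every comparison rests on 2 arrays, and the labels do not say whether these came from separate cultures. The 21 gene lists were not run.

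With the Feature Extraction log ratio, and identically with the series table, the called genes numbered 361 for UCCLBBS124 ethanol, 151 for UCCLBBS124 iso-alpha-acids, 99, 32 and 155 for UCCLBBS449 ethanol, pH4 and iso-alpha-acids, 564 for the ethanol difference and 428 for the iso-alpha-acid difference; the cause was not tested. A fold of at least 3 gave, by its construction, fewer genes: 26, 73 and 37 for UCCLBBS124 ethanol, pH4 and iso-alpha-acids, 6, 1 and 20 for UCCLBBS449, and 61, 67 and 57 for the differences. Adjusted p alone gave, by its construction, more: 1606, 1751 and 1471 for UCCLBBS124, 1682, 1621 and 1870 for UCCLBBS449, and 1773, 1743 and 1773 for the differences.

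Shared genes at a fold of at least 3 numbered 10 for ethanol with pH4, 0 for ethanol with iso-alpha-acids and 6 for pH4 with iso-alpha-acids in UCCLBBS124, 0 for ethanol with iso-alpha-acids in UCCLBBS449, and 0 for each stress between strains. With adjusted p alone they numbered 746, 530 and 880 in UCCLBBS124, 584 for ethanol with pH4, 743 for ethanol with iso-alpha-acids and 335 for pH4 with iso-alpha-acids in UCCLBBS449, and 501, 701 and 461 for ethanol, pH4 and iso-alpha-acids between strains. Leaving out 1 array gave 1 to 3 shared genes for ethanol between strains, with 3 without UCCLBBS124 ethanol replicate 2 and 2 without either UCCLBBS449 ethanol array; the cause was not tested. Leaving out 1 array gave 161 to 175, 192 to 247 and 73 to 101 called genes for UCCLBBS124 ethanol, pH4 and iso-alpha-acids, and 33 to 39, 13 to 16 and 69 to 78 for UCCLBBS449, where the remaining array is assumed to vary like the others of its strain.

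Against the 95th percentile of negative control spots, the share of UCCLBBS449 pF to pI probes above background was 40.2% for UCCLBBS124 pH4, 24.1% for UCCLBBS124 iso-alpha-acids and 23.8% for UCCLBBS449 iso-alpha-acids. The share of plain-number UCCLBBS124 probes was 44.9%, 93.9% and 90.1% for UCCLBBS124 ethanol, pH4 and iso-alpha-acids, and 59.7%, 62.5% and 91.1% for UCCLBBS449. The cause was not tested, and the same 2 pairs of arrays went against their label. Leaving out 1 array gave 12.3% or 40.5% for UCCLBBS124 ethanol in the plain-number probes.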

Other observations

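All tests in this part were chosen after the data were seen. Tags with a p and a letter, whose meaning the files do not give, were taken as groups. The 193 such UCCLBBS449 genes on the arrays labelled UCCLBBS124 ethanol, which carried UCCLBBS449 sequence, had a median log2 ratio of -0.35, with 2 called higher and 22 lower (camera adjusted p = 2.02e-08, or 0.389 with an estimated correlation; fry adjusted p = 0.0168). The median was -0.15 with median centring, so its size rests on the normalisation. At pH4, by the label UCCLBBS449, the 196 genes had a median of -0.20 and 0 were called (camera adjusted p = 9.30e-11, or 0.361 with an estimated correlation; fry adjusted p = 0.0157). On those labelled UCCLBBS449 ethanol the 194 genes had a median of 0.15, with 6 called higher and 2 lower (0.00553, or 0.744 with an estimated correlation; fry 0.0199). The 50 UCCLBBS124 pA genes had a median of -0.31 on the arrays labelled UCCLBBS124 iso-alpha-acids and 0.34 on those labelled UCCLBBS449 iso-alpha-acids, with camera adjusted p = 1.41e-06 and 2.38e-05, or 0.751 and 0.855 with an estimated correlation, and fry adjusted p = 0.0606 and 0.0291. For UCCLBBS124 pH4 their median was 0.27 (camera adjusted p = 0.00744, or 0.970 with an estimated correlation; fry adjusted p = 0.102). The shifts under iso-alpha-acids were not particular to UCCLBBS124 pA. On the same arrays UCCLBBS449 pA genes had medians of -0.28 (52 genes) and 0.27 (51 genes), though 0.04 for UCCLBBS124 pH4. Both pairs of iso-alpha-acid arrays carried UCCLBBS124 sequence, so the opposite signs are not a difference between the strains. None of the camera calls given here held with an estimated correlation, but that setting rests on 2 residual degrees of freedom and could hardly pass. On the arrays labelled UCCLBBS124 ethanol, the UCCLBBS449 pD genes had an estimated correlation of -0.00067, below the preset 0.01. Their camera p still went from 0.0539 to 0.169. The loss therefore does not show that correlation between genes accounts for the shifts. Fry does not compare a group with other genes.

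Some genes were called in opposite directions. Under the label UCCLBBS124, 12 genes were lower at pH4 (median -1.56) and higher under iso-alpha-acids (median 1.95), of which 11 were the run from UCCLBBS449_1407 to UCCLBBS449_1417. As 0 of 2453 genes differed by 2-fold between the stress-labelled channels of these comparisons, the difference lay in the control-labelled channels (median absolute 3.52 against 0.07). Whether these genes responded to the stresses in opposite ways therefore rests on which channel held the stress sample, which stays open. Under the label UCCLBBS449, 8 of the 9 genes in opposite directions were lower at pH4 and higher under iso-alpha-acids, such as UCCLBBS449_1899 (-1.20 and 2.22) and UCCLBBS449_2462 (-1.20 and 1.79). UCCLBBS449_0147 went the other way (1.01 and -1.03). The iso-alpha-acid arrays of that label carried UCCLBBS124 sequence, so these pairs of values also differ in genome. UCCLBBS449_2151 was called in 4 comparisons, at -1.55, -3.27 and -1.76 on the arrays labelled UCCLBBS124 ethanol, pH4 and iso-alpha-acids and at 1.07 on those labelled UCCLBBS449 iso-alpha-acids.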
